A study of Penicillium oxalicum with 18 samples.

How the data were processed

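The samples were mycelia of the filamentous fungus Penicillium oxalicum, from a wild-type strain and from a strain in which vib1 had been deleted. Per the labels' protocols, germinated cultures were grown for 24 h at 30 °C in medium with 2% glucose. The mycelia were then moved for 24 h to one of 3 media, with 2% glucose, with 2% N-acetylglucosamine (GlcNAc), or with 1% bran plus 1% microcrystalline cellulose. The growth protocol describes the glucose and the bran plus cellulose medium, and the GlcNAc medium is given by the sample labels and the design text. Each of the 6 combinations of strain and medium had 3 libraries, numbered in the labels, which makes 18. Groups were taken from the sample titles. Nothing in the labels says whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

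Per the labels' protocols, mRNA was bound on oligo(dT) beads, cDNA was cut with NlaIII, a short tag next to the cut was released with MmeI, and the tags were sequenced on an Illumina instrument. The values are FPKM, fragments per kilobase of gene model scaled by the mapped fragments, as the authors deposited them and per the file headers. How FPKM were computed from tag libraries, the aligner, the quantifier, the genome build and the gene lengths are not given in the sources used here. A tag library samples each transcript at few sites, so dividing by gene length affects comparisons between genes and not those of one gene between libraries. The table held 9176 gene models, of which 9146 had IDs starting with PDE and 30 had IDs starting with XLOC. The table gave no gene names, and the reference table available here (assembly ASM172317v3) uses other locus tags: 0 of the 9176 IDs matched any of its 9964 rows. The 23 keyword lists of gene functions fixed beforehand were therefore void, no gene list test was run, and genes appear under their IDs only.

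Read counts are unknown. Steps of a gene-specific size were fitted to the lowest values of 258 genes. Of 3019 values of up to 5 steps, 70.0% lay within 0.1 of a whole step, where evenly spread values give 20%. The 3019 include the values that set the steps, so the 20% is no fair baseline and steps are not established. The sizes of these steps put the relative depth of the libraries between 0.882 and 1.14, a ratio of 1.29. Only values close to a gene's lowest value entered this estimate, so it could hardly show larger differences in depth. Absolute depth, counting intervals and detection limits could not be given. Of 165168 values, 13701 were 0, and 415 of these zeros stood beside another replicate of the same group above 10 FPKM. An exact 0 can therefore be a failed estimate, and a gene at 0 in a group is only said to be listed at 0, with its values per library and no fold.

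Values were analysed as log2(FPKM + 1), a scale on which the differences of low genes are understated. Gene models with at least 1 FPKM in at least 3 libraries were tested (8455 tested, 721 left out). One linear model with 6 group means was fitted to all 18 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend and robust, 12 residual degrees of freedom), and plots were drawn with matplotlib 3.10.9. Tests were two-sided with Benjamini-Hochberg adjustment over genes. Groups listed wholly at 0 add no spread to the shared fit, which can make the p-values of such genes too small. A gene was called at an adjusted p under 0.05, and a second count required a difference of at least 1 log2 unit. The 11 comparisons were deletion against wild type in each medium and averaged over the 3 media, each other medium against glucose within each strain, and the differences of the deletion effect between media. Overlaps of gene lists are given beside the number expected from independent lists of the same sizes.

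These choices, the named-gene rule and most alternatives were fixed before the data were examined. With IDs that could not be paired with names, the rule allowed at most 2 genes higher and 2 lower per comparison: called genes with a mean of at least 10 FPKM in the higher group, no overlap between the libraries compared, and the largest log2 differences, with zeros entered as listed, so that the choice of some named genes rests on zeros. Genes and stretches of locus tags chosen after their values were seen are marked so in the text.

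The alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 10 FPKM, the ≥1 log2 threshold, median-ratio rescaling, quantile normalization, limma without trend and robust, limma array weights, only the groups compared, the replicate number as a block, and leaving out each replicate. Rescaling each library to the same total was added after the data were seen. A simulation drew independent normal noise with each gene's residual spread, equal in all libraries. Changes were put only into genes above 5 FPKM by their mean log2 value. For deletion against wild type in bran plus cellulose, glucose and GlcNAc, the test recovered 86.6%, 88.1% and 89.6% of changes of 1 log2 unit. Each share is over 67 changed genes, with 8455 genes tested. For changes of 0.5 log2 units, in 66 genes each, it recovered 54.6%, 48.5% and 56.1%. Of 169, 165 and 171 calls, 4.73%, 5.46% and 6.43% were false. In the real data many more genes were called and libraries differed in spread, so these shares need not hold there or for low genes.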

Results

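Vib1 is a transcription factor of filamentous fungi, known from Neurospora for its part in heterokaryon incompatibility and in the secretion of extracellular enzymes. By its title and design text, the study asked how its loss alters gene expression in Penicillium oxalicum, a fungus that secretes cellulases, on 3 carbon sources. The measured values were FPKM of 9176 gene models in 18 libraries, 3 for each strain in each medium. Glucose is a readily used sugar, GlcNAc is the monomer of chitin, and bran plus microcrystalline cellulose supplies plant polysaccharides. The FPKM of a library summed to between 915800 and 1119000, 713 to 860 gene models were listed at 0 in a library, and no 2 replicates were identical. Read depth is unknown. Estimated relative depth spanned a factor of 1.29, by a method that could hardly show more.

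The deleted gene could not be looked up, because the IDs of the table are not paired with gene names. A fixed search for gene models under 1 FPKM in all 9 deletion libraries and over 10 FPKM in all 9 wild-type libraries found 0 among the 5498 gene models over 10 FPKM in all wild-type libraries. The nearest of these 5498, PDE_00667, was chosen after its values were seen: it reached at most 2.21 FPKM in a deletion library and at least 26.2 FPKM in a wild-type library. The search could not find a gene of low expression. PDE_02204 and PDE_03474, also chosen after their values were seen, were listed at 0 in all 9 deletion libraries. They were above 0 in all 9 wild-type libraries, at most at 2.06 and 2.79 FPKM. No gene model is called vib1 here, and a 3' tag outside a deleted part would not test the deletion. The strain labels thus have no check from the targeted gene.

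The deletion strain in glucose, the deletion strain in GlcNAc and wild type in GlcNAc each stood apart from the other groups. The first principal component (38.0% of the variance) set off the deletion strain in glucose at one end and, less far, wild type in GlcNAc at the other, and the second (24.9%) set off the deletion strain in GlcNAc. In bran plus cellulose both strains lay close to each other. The root mean square log2 difference between the strains was 0.60 in bran plus cellulose, 1.34 in glucose and 1.40 in GlcNAc. The change from glucose to bran plus cellulose measured 0.86 in wild type, and the change from glucose to GlcNAc measured 0.99. Spearman correlations between replicates were at least 0.968, the lowest being between replicates 1 and 3 of wild type in bran plus cellulose. The highest between libraries of different groups was 0.973, in that medium, between wild-type replicate 2 and deletion replicate 3. Some libraries of opposite strains there thus correlated better than some replicates. Replicate 3 of wild type in bran plus cellulose had the largest residual spread of all libraries, 0.38 log2 units.

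**Figure D1:**
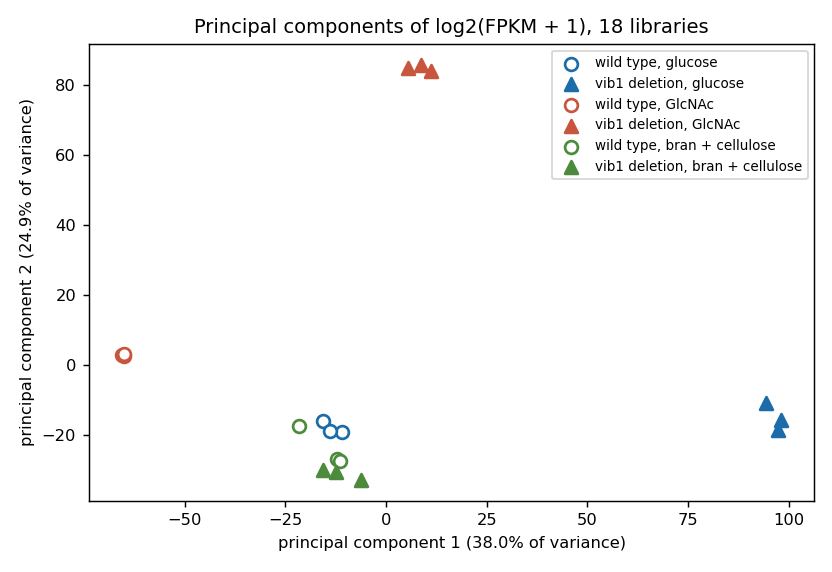
Principal components 1 (38.0% of the variance, x axis) and 2 (24.9%, y axis) of log2(FPKM + 1), with 1 point per library, colours for media and open circles for wild type, filled triangles for the vib1 deletion. The 3 deletion libraries in glucose lie far right, the 3 wild-type libraries in GlcNAc far left, the 3 deletion libraries in GlcNAc lie at the top, and the libraries of both strains in bran plus cellulose lie near each other.

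In bran plus cellulose, the medium with plant polysaccharides, fewer genes differed between the strains than in the other media. PDE_07655 rose from 1.26 ± 0.883 FPKM (SD, n = 3) in wild type to 159 ± 32.1 in the deletion strain, a log2 difference of 6.20 ± 0.304 (SE; limma adjusted p = 4.06e-09). PDE_06813 rose from 31.1 ± 18.3 to 794 ± 109.7 FPKM (4.86 ± 0.425, adjusted p = 1.38e-06). PDE_01252 fell from 2851 ± 854 to 72.9 ± 15.0 FPKM (log2 difference −5.25 ± 0.237, adjusted p = 1.97e-09). PDE_07927 fell from 1816 ± 291 to 47.5 ± 6.29 FPKM (−5.22 ± 0.135, adjusted p = 4.02e-12). In all, 2258 of 8455 genes were called, 1114 higher and 1144 lower in the deletion strain, and 467 of them by at least 1 log2 unit, 198 higher and 269 lower. A fit to the 6 libraries of this medium alone called 1218 genes. With a pseudocount of 5 the count at 1 log2 unit was 300.

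**Figure D2:**
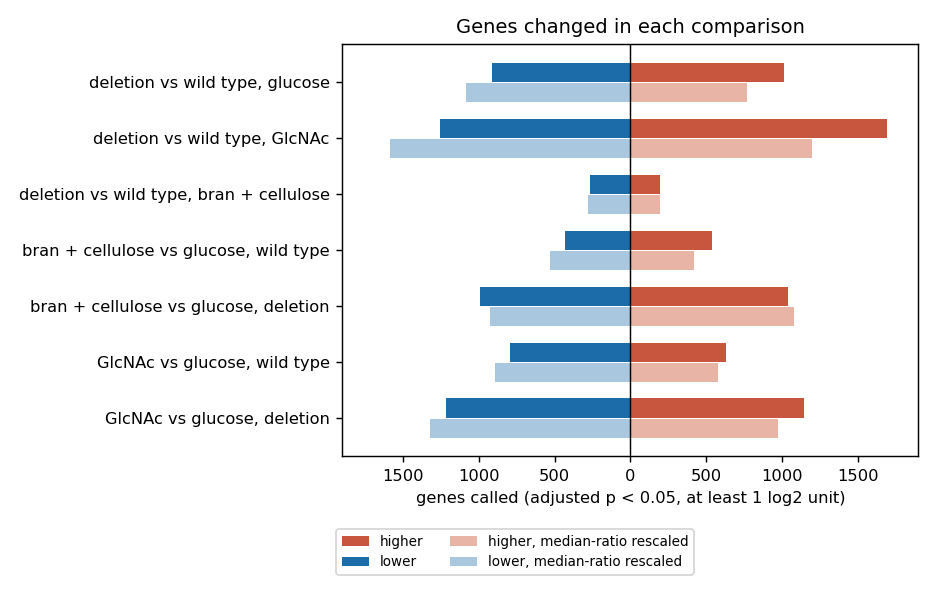
Number of genes called with a difference of at least 1 log2 unit (x axis, higher to the right and lower to the left of 0) in 7 comparisons, for FPKM as deposited (dark bars) and after median-ratio rescaling (light bars). Deletion against wild type gave 467 genes in bran plus cellulose, 1926 in glucose and 2950 in GlcNAc.

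In glucose, some of the wild type's abundant transcripts fell to a few FPKM or less in the deletion strain. PDE_02125 fell from 4978 ± 352 FPKM to 3.75 ± 1.52 (log2 difference −10.09 ± 0.21, SE; limma adjusted p = 3.86e-15). PDE_04495 fell from 1294 ± 134 to 0.493 ± 0.389 FPKM (−9.79 ± 0.158, adjusted p = 1.6e-16). PDE_03927 rose from 0.553 ± 0.362 to 187 ± 59.7 FPKM (6.90 ± 0.379, adjusted p = 7.23e-10). PDE_08497 was listed at 0 in all 9 wild-type libraries and stood at 141, 221 and 128 FPKM in the deletion libraries in glucose (adjusted p = 4.76e-13). PDE_09832 and PDE_09831, chosen after their values were seen as 2 very abundant transcripts, also fell. PDE_09832 went from 60400 ± 4792 FPKM to 1672 ± 1214 (−5.44 ± 0.351, adjusted p = 4.1e-09) and PDE_09831 from 25430 ± 2434 to 779 ± 485 (−5.23 ± 0.304, adjusted p = 1.27e-09). Neither was called in the other media, where the wild-type and deletion means of PDE_09832 were 53960 and 69180 FPKM in bran plus cellulose and 93020 and 88180 FPKM in GlcNAc.

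Of 5480 genes called in glucose, 3556 were higher and 1924 lower in the deletion strain, and 1926 differed by at least 1 log2 unit, 1016 higher and 910 lower. The median of all genes lay 0.18 log2 units higher in the deletion strain. Relative to the median gene, by median-ratio rescaling, 2593 were higher and 2624 lower, with 769 higher and 1083 lower by at least 1 log2 unit. Rescaling to the same total gave 1261 higher and 815 lower by at least 1 log2 unit. The named genes, which were picked for their large differences, kept their direction under every scaling tried.

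GlcNAc gave the largest number of differences between the strains. PDE_02095 stood at 2098, 2038 and 2517 FPKM in wild type and was listed at 0 in all 3 deletion libraries (limma adjusted p = 9.82e-10). PDE_06443 stood at 798, 929 and 995 FPKM in wild type and was likewise listed at 0 in the deletion strain (adjusted p = 2.63e-11). In the other direction, PDE_08440 was listed at 0 in the 3 wild-type libraries and at 194, 232 and 253 FPKM in the deletion libraries (adjusted p = 1.77e-11). PDE_04964 was listed at 0 in wild type and at 145, 146 and 136 FPKM in the deletion strain (adjusted p = 1.15e-16), while in the other media both strains had between 66.9 and 96.5 FPKM of it. Because an exact 0 may be a failed estimate, no fold is given for these 4 genes. Of 6302 genes called in GlcNAc, 3789 were higher and 2513 lower, and 2950 differed by at least 1 log2 unit, 1691 higher and 1259 lower. The median of all genes lay 0.20 log2 units higher in the deletion strain, and relative to it 3061 were higher and 3211 lower, with 1198 higher and 1588 lower by at least 1 log2 unit. Rescaling all libraries to the same total gave 2226 higher and 1007 lower by at least 1 log2 unit.

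A smaller group of genes differed between the strains in the same direction in all media. PDE_00969 averaged 136 ± 69.8 FPKM in wild type and 2.97 ± 1.42 in the deletion strain in bran plus cellulose, 129 ± 3.40 and 2.12 ± 0.0361 in glucose, and 3783 ± 110.1 and 27.9 ± 2.05 in GlcNAc (average log2 difference −5.83 ± 0.161, SE; limma adjusted p = 1.99e-13). PDE_00667 differed on average by −5.34 ± 0.2 log2 units (adjusted p = 6.79e-12). In wild type it rose to between 403 and 444 FPKM in GlcNAc, and in the deletion strain in GlcNAc its 3 values were 1.78, 0 and 1.02 FPKM. PDE_04788 and PDE_03190 were listed at 0 in all 9 wild-type libraries and above 0 in all 9 deletion libraries, at 1.65 to 57.8 and at 5.71 to 27.4 FPKM (adjusted p = 1.05e-10 and 2.01e-13). The average over the media does not require one direction: PDE_04495 differed by −3.27 log2 units on average and by 0.79 in bran plus cellulose. Averaged over the media 6234 genes were called, 3926 higher and 2308 lower. Of these, 1161 differed by at least 1 log2 unit, 471 higher and 690 lower. These counts therefore include genes whose direction differed between media. The median gene shifted by 0.14. After median-ratio rescaling 3006 genes were called higher and 3078 lower, and the split at 1 log2 unit was 340 higher and 813 lower. At 1 log2 unit, rescaling all libraries to the same total gave 615 higher and 587 lower, and a pseudocount of 5 left 765 genes.

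**Figure D3:**
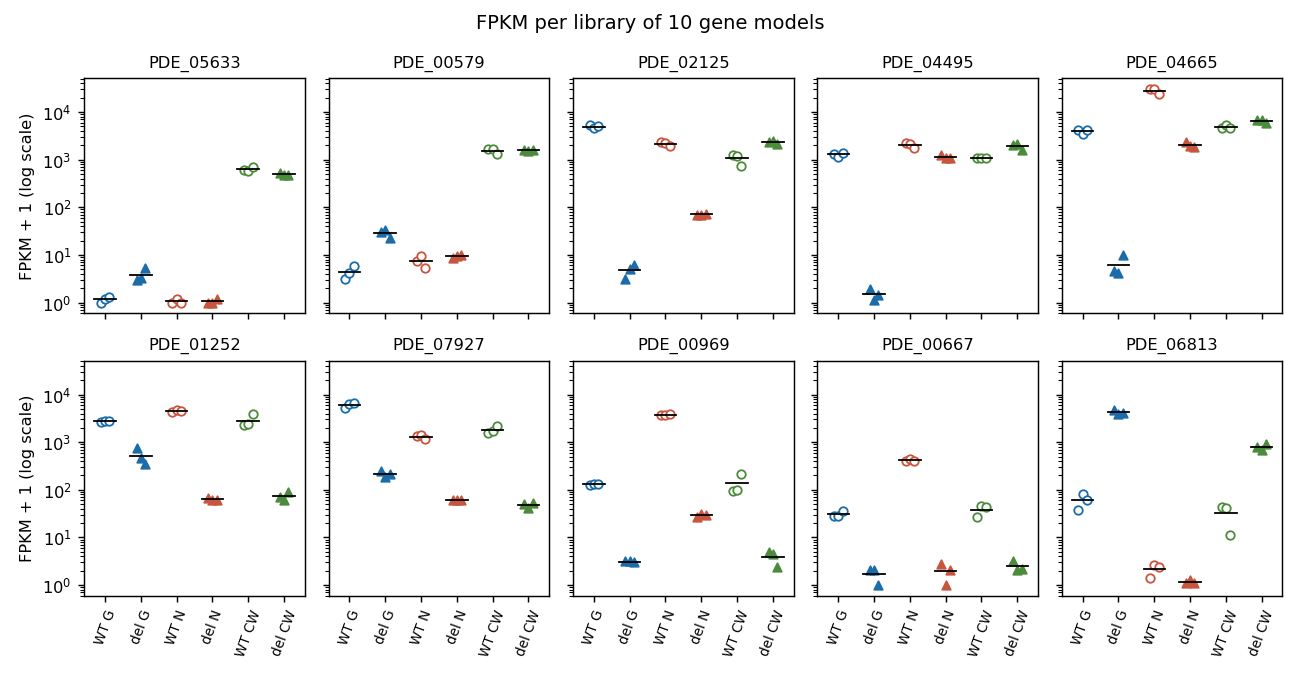
FPKM + 1 on a log axis of 10 gene models in the 18 libraries, by strain (open circles wild type, WT; filled triangles vib1 deletion, del) and medium (G glucose, N GlcNAc, CW bran plus cellulose), with black lines at the group means. PDE_05633 and PDE_00579 are high in both strains in bran plus cellulose, PDE_04495 is near 0 only in the deletion strain in glucose, and PDE_07927, PDE_00969 and PDE_00667 are lower in the deletion strain in each medium.

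At a difference of at least 1 log2 unit in each of the 3 media, 50 genes were lower and 15 higher in the deletion strain, where independent lists would share 4.31 and 4.76. The 15 became 7 without replicate 3 of wild type in bran plus cellulose and 5 with a pseudocount of 5, which left 38 of the 50, so the higher group depends on these choices. Glucose and GlcNAc shared 502 lower genes (136 expected of independent lists) and 413 higher genes (203 expected, and 262 shared after median-ratio rescaling or 257 with a pseudocount of 5). The 262 came from lists of 769 and 1198 higher genes, shorter than the 1016 and 1691 behind the 203. Expected numbers in this paragraph belong to the lists as reported and not to the refits. Of the 198 genes higher in bran plus cellulose, 58 were also higher in glucose (23.8 expected) and 66 were lower there (21.3 expected); a pseudocount of 5 left 35 and 43. In GlcNAc 29 of them were higher (39.6 expected, and 18 higher in both without replicate 3 of wild type in bran plus cellulose) and 95 were lower (29.5 expected); a pseudocount of 5 left 15 and 59. Of the 269 genes lower in bran plus cellulose, 104 were also lower in glucose (28.9 expected) and 84 in GlcNAc (40.1 expected), while 24 were higher in glucose (32.3 expected) and 71 higher in GlcNAc (53.8 expected). These pairs of comparisons share no libraries. Across genes, which are not independent replicates, the log2 differences in glucose and GlcNAc had a Pearson r of 0.408, against 0.0860 for bran plus cellulose with glucose and −0.0473 for bran plus cellulose with GlcNAc. Leaving out replicate 3 of wild type in bran plus cellulose gave 0.0407 in place of 0.0860, and leaving out replicate 3 of the deletion strain in that medium gave −0.0781 in place of −0.0473.

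The wild type's own response to the media gives the background for the strain differences. On bran plus cellulose against glucose, PDE_05633 rose from 0.163 ± 0.165 to 628 ± 70.04 FPKM (log2 difference 9.08 ± 0.171, SE; limma adjusted p = 1.01e-14) and PDE_00579 from 3.41 ± 1.45 to 1555 ± 194 FPKM (8.51 ± 0.225, adjusted p = 4.86e-13). In the deletion strain on the same medium these genes stood at 499 ± 26.5 and 1584 ± 56.6 FPKM, and the strain difference was not called (limma adjusted p = 0.172 and 0.94). PDE_01629 fell from 739 ± 34.2 to 1.35 ± 0.314 FPKM (−8.30 ± 0.168, adjusted p = 1.65e-14). PDE_08756 stood at 309, 212 and 338 FPKM in wild type in glucose and was listed at 0 in wild type on bran plus cellulose (adjusted p = 3.23e-12) and in all 9 deletion libraries. Of 4083 genes called, 965 differed by at least 1 log2 unit, 535 higher and 430 lower. The median shift was 0.14, and relative to it 418 were higher and 529 lower; a pseudocount of 5 left 630 genes.

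On GlcNAc against glucose in wild type, PDE_01737 rose from 0.34 ± 0.555 to 306 ± 24.0 FPKM (log2 difference 7.91 ± 0.851, SE; limma adjusted p = 2.2e-06). PDE_08250 was above 0 in the wild-type GlcNAc libraries only, at 177, 186 and 160 FPKM (adjusted p = 4.68e-16). In the deletion strain in GlcNAc, PDE_01737 stood at 3.03, 0 and 4.54 FPKM and PDE_08250 was listed at 0. PDE_01629 fell here too, to 3.55 ± 0.379 FPKM (−7.35 ± 0.168, adjusted p = 9.64e-14), and PDE_03530 fell from 120.5 ± 10.4 to 0.347 ± 0.600 FPKM (−6.58 ± 0.232, adjusted p = 1.47e-11). Of 4992 genes called, 1429 differed by at least 1 log2 unit, 632 higher and 797 lower.

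In the deletion strain the same changes of medium moved more genes. From glucose to bran plus cellulose, PDE_04495 rose from 0.493 ± 0.389 to 1911 ± 269.5 FPKM (log2 difference 10.35 ± 0.158, SE; limma adjusted p = 1.05e-16) and PDE_04665 from 5.14 ± 3.16 to 6527 ± 524 FPKM (10.17 ± 0.235, adjusted p = 1.23e-14). In wild type both genes stood at 1092 FPKM or more in all 9 libraries. PDE_01629 fell from 833 ± 220 to 1.23 ± 0.345 FPKM (−8.53 ± 0.168, adjusted p = 1.75e-15), close to its values in wild type. PDE_08440 fell from 276, 271 and 288 FPKM to being listed at 0 (adjusted p = 8.88e-12). This comparison called 5289 genes, 2404 higher and 2885 lower, with 2026 at 1 log2 unit (1037 higher, 989 lower; 931 and 1185 after rescaling to the same total). From glucose to GlcNAc, PDE_03475 rose from 0.38 ± 0.185 to 1616 ± 438 FPKM (10.16 ± 0.817, adjusted p = 4.75e-08), and PDE_04495 rose to 1157 ± 97.5 FPKM (9.63 ± 0.158, adjusted p = 3.73e-16). PDE_06813 fell from 4222 ± 372 to 0.18 ± 0.0954 FPKM (−11.81 ± 0.425, adjusted p = 5.31e-12), and PDE_06802 fell from 3858, 3379 and 2590 FPKM to being listed at 0 (adjusted p = 1.55e-12). This comparison called 5811 genes, with 2363 at 1 log2 unit (1145 higher, 1218 lower; relative to a median shift of 0.17, 973 and 1324).

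The wild type's medium responses were carried over in part. Of the 535 genes that rose by at least 1 log2 unit on bran plus cellulose in wild type, 288 were called higher in the deletion strain as well (152 expected of independent lists) and 101 were called lower (183 expected); their median log2 difference was 1.40 in wild type and 0.66 in the deletion strain. Of the 430 genes that fell, 254 were called lower (147 expected) and 100 higher (122 expected), with medians of −1.56 and −0.99. For GlcNAc, 319 of 632 higher genes (264 expected) and 520 of 797 lower genes (215 expected) were called in the same direction in the deletion strain, and 112 (171 expected) and 139 (333 expected) in the opposite one. Selection on the wild-type values enlarges the wild-type medians.

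The deletion effect itself differed between media in the interaction tests, the difference of 2 strain differences. PDE_02125 was lower in the deletion strain in glucose, as given above, and higher in bran plus cellulose (1066 ± 277 FPKM in wild type, 2301 ± 163 in the deletion strain), so that the effects differed by 11.23 ± 0.297 log2 units (SE; limma adjusted p = 1.14e-13). PDE_00803 went from 505 ± 12.8 to 0.447 ± 0.502 FPKM in glucose and from 50.6 ± 16.5 to 256 ± 35.6 FPKM in bran plus cellulose (10.87 ± 0.330, adjusted p = 5.81e-13). PDE_08298 stood at 0, 0 and 5.08 FPKM in wild type in glucose and at 216 ± 12.3 FPKM in the deletion strain, against 179 ± 25.2 and 124 ± 1.92 FPKM in bran plus cellulose (−7.41 ± 0.686, adjusted p = 5.79e-07). PDE_08478 was listed at 0 in wild type in glucose and in the deletion strain in bran plus cellulose, with 25.6, 41.9 and 47.4 FPKM in the deletion strain in glucose and 7.66, 6.05 and 1.21 FPKM in wild type in bran plus cellulose (adjusted p = 3.56e-08). Between bran plus cellulose and glucose 4423 genes differed in their strain effect, 1919 of them by at least 1 log2 unit, 799 higher and 1120 lower in bran plus cellulose. The median of these differences was −0.19, and after median-ratio rescaling 950 were higher and 878 lower.

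Between GlcNAc and glucose, PDE_02128 differed in its strain effect by 9.57 ± 0.254 log2 units (SE; limma adjusted p = 2.18e-13): in glucose it fell from 1452 ± 79.9 to 1.65 ± 0.918 FPKM, and in GlcNAc the strains had 687 ± 85.6 and 914 ± 10.7 FPKM. PDE_04495 differed by 8.98 ± 0.223 (adjusted p = 1.45e-13), with 2036 ± 236 FPKM in wild type and 1157 ± 97.5 in the deletion strain in GlcNAc. PDE_06802 rose in glucose from 608 ± 52.8 FPKM to 3276 ± 640 and in GlcNAc went from 380, 351 and 259 FPKM to being listed at 0 (adjusted p = 4.27e-10). PDE_02095 had 782 ± 120.1 and 346 ± 30.6 FPKM in glucose and was listed at 0 in the deletion strain in GlcNAc only (adjusted p = 3.14e-07). In this comparison 5014 genes were called, 2483 of them by at least 1 log2 unit (1294 higher, 1189 lower in GlcNAc; 1210 and 1232 after median-ratio rescaling, 1453 and 1087 after rescaling to the same total).

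Between bran plus cellulose and GlcNAc, PDE_02095 and PDE_06802, both listed at 0 in the deletion strain in GlcNAc, differed in their strain effect (limma adjusted p = 1.25e-07 and 1.11e-09). In bran plus cellulose PDE_02095 ranged from 200.1 to 2939 FPKM among the 3 wild-type libraries and from 401 to 944 FPKM among the deletion libraries. PDE_00845 was listed at 0 in wild type in GlcNAc and in the deletion strain in bran plus cellulose, and stood at 62.7, 80.7 and 66.4 FPKM in the deletion strain in GlcNAc and at 15.7, 11.7 and 26.2 FPKM in wild type in bran plus cellulose (adjusted p = 6.04e-11). PDE_03475 rose in GlcNAc from 24.2 ± 5.02 FPKM to 1616 ± 438 and had 1.64 ± 0.209 FPKM in the deletion strain in bran plus cellulose, where the wild-type libraries had 7.04, 5.28 and 143 FPKM (−8.87 ± 1.16, adjusted p = 9.92e-06). The test called 5668 genes, 3117 by at least 1 log2 unit, 1299 higher and 1818 lower in bran plus cellulose. The median was −0.20, and after median-ratio rescaling 1593 were higher and 1405 lower; rescaling to the same total gave 1043 and 2356.

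PDE_00803 lies in a stretch of locus tags that changed together, chosen after its values were seen. Its ends are those of a run of genes all called lower by at least 1 log2 unit in glucose. The count in glucose thus follows from the choice. All 23 gene models from PDE_00789 to PDE_00811 were called lower in the deletion strain in glucose (median log2 difference −7.03, range −9.27 to −3.79). In GlcNAc 22 of the 23 were called lower (median −2.18). In bran plus cellulose all 23 were called higher (median 1.24, range 0.70 to 2.37). The mean per gene of the stretch was 278 ± 20.5 FPKM (SD, n = 3) in wild type and 0.778 ± 0.114 in the deletion strain in glucose. It was 335 ± 12.9 and 66.2 ± 0.793 FPKM in GlcNAc, and 87.1 ± 7.82 and 211 ± 22.9 FPKM in bran plus cellulose. The directions in glucose and bran plus cellulose held for all 23 under median-ratio rescaling, quantile normalization and rescaling to the same total; in GlcNAc 21 were called lower and 1 higher under the last of these. Positions in the genome are not given in the sources used here, so adjacency is known only from the numbering.

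**Figure D4:**
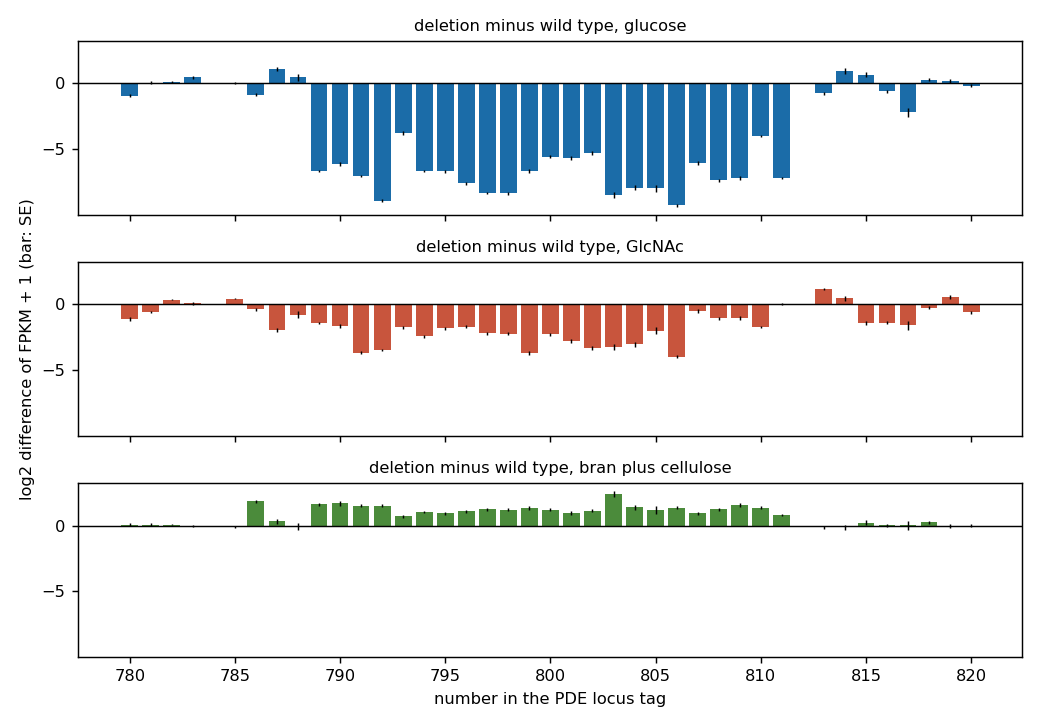
Log2 difference of FPKM + 1, deletion minus wild type (y axis, bars; error bars are SE), for tested gene models in the order of their PDE locus tag numbers (x axis) in glucose, GlcNAc and bran plus cellulose. The 23 models from PDE_00789 to PDE_00811 are lower in glucose, with a median of −7.03, and higher in bran plus cellulose, with a median of 1.24.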

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

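The test of exchanged strain labels, the test of the FPKM total and the permutation of residuals were chosen after the results were seen. The results listed here were picked out because the effect of the vib1 deletion differed between media by a test of that difference. Between bran plus cellulose and glucose 4423 genes differed in their strain effect, between GlcNAc and glucose 5014, and between bran plus cellulose and GlcNAc 5668. For the first, the limma adjusted p was 1.14e-13 for PDE_02125, 5.81e-13 for PDE_00803, 3.56e-08 for PDE_08478 and 5.79e-07 for PDE_08298. For the second, it was 2.18e-13 for PDE_02128, 1.45e-13 for PDE_04495, 4.27e-10 for PDE_06802 and 3.14e-07 for PDE_02095. For the last, it was 1.25e-07 for PDE_02095, 1.11e-09 for PDE_06802, 6.04e-11 for PDE_00845 and 9.92e-06 for PDE_03475.

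Other splits of the libraries were tried for each count of called genes. For the 7 comparisons of 3 libraries against 3, the 10 possible splits cannot give a share under 0.05, and the real split was the 1 split with the highest count each time. The real count and the highest of the others were 2258 and 8 for deletion against wild type in bran plus cellulose, 5480 and 1 in glucose, and 6302 and 1 in GlcNAc. They were 4083 and 2 for bran plus cellulose against glucose in wild type, 4992 and 1 for GlcNAc against glucose in wild type, and 5289 and 2, and 5811 and 0, for the same media in the deletion strain. For the strain effect averaged over media, 1 of 100 splits, the real one, reached 6234 genes, and the highest other split, which kept the real labels in 2 of 3 media, called 5767. The splits over several media kept at least 2 of the 3 libraries of each strain under the real label in each medium. None thus reversed the labels of a whole medium, and the shares hold only among such splits. For the differences between media, 1 of 100 splits reached the real 4423, 5014 and 5668 genes. The highest others called 4259, 3472 and 5272 and kept the real labels in 1 of 2 media, so a high count under another split reflects the strain difference left in that medium. For the averaged effect, random strain labels can be excluded at a share under 0.05 among splits of this kind only. If the replicates are technical, the splits cannot exclude chance differences between cultures. For the differences these splits test only for no strain effect in either medium. An equal effect in both media was tested by permuting the residuals of a fit of strain plus medium over the 12 libraries, 99 times. Of 100 counts, the real one included, 1 reached 4423 genes (highest other 2496), 2 reached 5014 (highest other 5245) and 1 reached 5668 (highest other 3650). An equal effect can be excluded on the deposited scale at a share under 0.05 for each. This takes residuals as exchangeable between groups and replicates as separate cultures.

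The strains differed by at least 1 log2 unit in 467 genes in bran plus cellulose, against 1926 in glucose and 2950 in GlcNAc. A single divergent library, such as replicate 3 of wild type, is not the whole cause: leaving out 1 library gave at most 550 genes in bran plus cellulose and at least 1900 in the other media. The median relative depth was 0.959 times that of the other libraries. The estimate could hardly show a large difference, so it does not decide whether depth was lower. An exchanged pair of strain labels would make another split of the 6 libraries call more genes than the labelled one, and the highest of the other 9 called 8. A score over 224 genes that differ in glucose and GlcNAc did not separate the strains in this medium, with 1 library on the wrong side, and decides nothing. A weaker dependence on Vib1 in bran plus cellulose is a candidate explanation, raised from the same data and not tested. Part of the effects turned rather than weakened. Of the 198 genes higher there, 66 were lower and 58 higher in glucose, and 95 were lower and 29 higher in GlcNAc. Of the 269 genes lower there, 104 were lower and 24 higher in glucose, and 84 were lower and 71 higher in GlcNAc. Differences between media in growth state and in depth are left open.

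In glucose and GlcNAc more genes were called higher than lower in the deletion strain. The column total was tested by rescaling every library to the same total, which left the median gene 0.31 log2 units higher in glucose and 0.42 in GlcNAc. Leaving out the 20 most abundant genes, which took 17.3% of the total in wild type and 11.8% in the deletion strain in glucose, left medians of 0.22 and 0.43. Neither thus accounts for the shift by itself. The share of fragments outside the listed gene models, by which FPKM may also be scaled, and the amount of mRNA per cell were not measured, so the direction of the median gene stays open, and the splits on the deposited scale depend on it.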

How the results depend on the processing

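Rescaling all libraries to the same total, and all refits of PDE_09832, of PDE_09831, of the stretch from PDE_00789 to PDE_00811 and of the overlaps in opposite directions, were added after the data were seen; the others were planned. The split of higher against lower counts moved with the scaling. All 44 results for named genes kept direction and call in 528 refits, with limma adjusted p up to 0.00463. So did PDE_09832 and PDE_09831 in glucose, with limma adjusted p up to 0.000268 and 0.00018. The named genes were picked for large differences without overlap, for differences between media in at least 1 medium, so their result was nearly fixed in advance. No refit removed the zeros, so none tests whether a 0 was a failed estimate. The stretches were refitted less widely: the one from PDE_00789 to PDE_00811 under the scalings only, where in GlcNAc 22 lower calls became 21 lower and 1 higher with the same total, and the others not at all. Counts of called genes per comparison stayed within 1.5 times of the reported ones, with these exceptions. Requiring 1 log2 unit left 467, 1926, 2950 and 1161 genes for deletion against wild type in bran plus cellulose, glucose, GlcNAc and averaged. It left 965 and 1429 for bran plus cellulose and GlcNAc against glucose in wild type, 2026 and 2363 in the deletion strain, and 1919, 2483 and 3117 for the differences of the strain effect; this follows from the added threshold. Fitting only the groups compared gave 1218 genes in bran plus cellulose. That fit leaves as few libraries in glucose and GlcNAc. There no alternative without the 1 log2 threshold gave under 4975 and 5647 genes. Fewer samples thus do not account for the drop by themselves, and its cause was not tested. A pseudocount of 5 gave 300 genes at 1 log2 unit in bran plus cellulose, 765 averaged and 630 for bran plus cellulose against glucose in wild type, because it shrinks the differences of low genes. Leaving out single replicates moved no count of called genes per comparison by over 1.5 times: at 1 log2 unit the ranges were 401 to 550 in bran plus cellulose, 1900 to 1940 in glucose and 2891 to 2970 in GlcNAc. Without replicate 3 of wild type in bran plus cellulose, 401 genes were called there, 358 of them among the 467, while the genes higher in all 3 media dropped from 15 to 7 and those higher in both bran plus cellulose and GlcNAc from 29 to 18. Those 15 genes became 5 with a pseudocount of 5, 9 with only the groups compared and 7 with array weights. The 413 higher genes shared by glucose and GlcNAc became 257 with a pseudocount of 5 and 262 after median-ratio rescaling. That rescaling also shortened the 2 lists of higher genes, from 1016 and 1691 to 769 and 1198, so fewer shared genes would be expected. The cause of these drops was not tested. Of the genes higher in bran plus cellulose, the 58 also higher in glucose became 35 with a pseudocount of 5, and the 29 also higher in GlcNAc became 15 with a pseudocount of 5, 15 with array weights and 18 with only the groups compared. The 66 lower in glucose and the 95 lower in GlcNAc became 43 and 59 with a pseudocount of 5. The correlation of strain effects ranged from 0.0355 (array weights) to 0.102 (pseudocount of 5) for bran plus cellulose with glucose and from −0.0798 (array weights) to −0.0293 (pseudocount of 5) with GlcNAc.

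Replicate numbers did not pair the libraries: over 45 pairs with the same number the correlation of deviations ran from −0.107 to 0.181 (median 0.00627, 4 pairs over 0.1), and 8 of 18 libraries correlated best with their own number. The fit with the replicate number as a block called 2233, 5486 and 6315 genes for deletion against wild type in bran plus cellulose, glucose and GlcNAc and 6245 averaged. With the block, bran plus cellulose against glucose called 4074 in wild type and 5268 in the deletion strain, GlcNAc against glucose 4995 and 5829, and the differences of the strain effect 4423, 5005 and 5639. The block changed no call of a named gene. Gene list tests were not run, since no list could be matched to the IDs, and tests on counts were not run on FPKM. Absolute depth is unknown, which limits what an exact 0 means.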

Other observations

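The counts of stretches and of switched genes were chosen after the data were seen; the test of stretches by genes 3 numbers apart was planned before its result. Beyond the stretch from PDE_00789 to PDE_00811, other stretches of consecutive locus tags changed together. Those of 12, 13 and 11 models were likewise bounded by their calls in glucose, so their counts there follow from the choice. The 12 models from PDE_09999 to PDE_10010 were all called lower in the deletion strain in glucose (median log2 difference −7.07). Their mean per gene went from 199 ± 16.7 FPKM (SD, n = 3) to 0.345 ± 0.078 there, from 281 ± 14.9 to 117.6 ± 9.47 in GlcNAc, and from 107 ± 5.51 to 163 ± 15.7 in bran plus cellulose, where 10 were called higher. The 13 models from PDE_09231 to PDE_09243 averaged 3535 ± 217 FPKM in wild type in glucose and 1117 ± 907 in the deletion strain, all 13 called lower. In GlcNAc they went from 172 ± 27.2 to 2.95 ± 0.114 FPKM, with 12 called lower, and in bran plus cellulose 0 of 13 were called by limma (1 at an unadjusted p under 0.05), with 1224 ± 384 and 1808 ± 215 FPKM. In the other direction, the 11 models from PDE_04019 to PDE_04029 rose in glucose from 34.3 ± 0.65 to 108 ± 19.2 FPKM, all 11 called higher. In GlcNAc 5 were called higher, with 28.0 ± 0.96 and 46 ± 2.13 FPKM, and 0 were called in bran plus cellulose (0 at an unadjusted p under 0.05), with 48.3 ± 6.59 and 48.5 ± 1.21 FPKM. Stretches could also turn: the 4 models from PDE_07205 to PDE_07208 were higher in glucose (median 2.23) and lower in GlcNAc (median −2.03).

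Across the table, runs of at least 4 consecutive numbers that all differed by at least 1 log2 unit in the same direction numbered 26 in glucose (9 higher, 17 lower, 159 genes), 34 in GlcNAc (18 higher, 16 lower, 171 genes) and 4 in bran plus cellulose (all higher, 19 genes). In 1000 permuted gene orders the highest numbers were 6, 19 and 1 (permutation p = 0.001 in each medium, the smallest they can give). All runs in bran plus cellulose but the one from PDE_09757 to PDE_09761 are pieces of the stretch from PDE_00789 to PDE_00811. The count in that medium thus largely restates that stretch. If reads shared by adjacent models made the pattern, genes 3 numbers apart would not be correlated. Their log2 differences had an r of 0.177 in glucose, above all permuted orders (highest 0.0430), so shared reads do not explain the whole pattern. No source used here gives what these genes encode, where they lie or where Vib1 binds, so no biological explanation was tested.

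Some genes switched between being listed at 0 in all 3 libraries of one strain and at least 50 FPKM in all 3 of the other. In glucose 2 were at 0 in wild type and 9 in the deletion strain, in GlcNAc 8 and 9, and in bran plus cellulose 0 and 0. With at least 10 FPKM required instead, the numbers were 19 and 22 in glucose, 25 and 41 in GlcNAc, and 1 and 2 in bran plus cellulose. By contrast, PDE_02204 and PDE_03474 were listed at 0 in all 9 deletion libraries and were above 0 in all 9 wild-type libraries, at most at 2.06 and 2.79 FPKM.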
